A study of Arabidopsis thaliana with 111 samples.

How the data were processed

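Seeds of Arabidopsis thaliana, accession Columbia-0, were sown on 0.7% water agarose and kept at 22 °C in continuous light, per the labels. They were dissected under a microscope into endosperm of the micropylar and the chalazal end (MCE), the rest of the endosperm (PE), the radicle with the axis of the embryo (RAD) and cotyledons (COT). Whole dry seeds were taken as well. Seeds were sorted at 25 h by rupture of the testa and at 38 h by rupture of the endosperm. Total RNA was amplified and labelled with biotin from 100 ng per sample with an Affymetrix kit that primes at the 3' end, per the labels. No 3' bias or probe level measure was analysed here.

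The deposited values were 1 table of log2 expression values with 1 column per array and 1 line per locus. Per the submitters' processing notes, RMA and the package affy were used, with versions that were not given. RMA subtracts background, normalizes arrays together and summarises the probes of each locus. The definition that assigned probes to loci, the genome build and any filter were not given in the sources used here, so no positions are printed. Each locus had 1 probe set. The array medians lay between 4.67 and 5.22 and the upper quartiles between 7.19 and 7.42 and the lowest values between 1.94 and 2.27, which was checked as fitting a log2 scale. Symbols came from the reference table of the organism, in which 21205 loci were found and 108 were not, and loci without a symbol there go by their locus name. No control probe sets were in the table, and no 2 arrays were identical.

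Each array was placed in 1 of 28 groups by its title. For 3 arrays, MCE at 16 h replicate 2, MCE at 20 h replicate 2 and MCE at 25 h without testa rupture replicate 2, the source name in the labels named another group than the title, and 6 arrays were described there as redone for quality control: MCE at 7 h replicate 2, 12 h replicate 2, 25 h without testa rupture replicate 1 and 31 h replicate 4, RAD at 7 h replicate 3 and COT at 3 h replicate 2. All were kept, and fits without either set are among the alternatives. Groups held 4 arrays, except PE at 3 h with 3. Whether replicates came from separate seed batches was not given, so the p-values measure the spread between these samples. The number of arrays limits the precision, with a typical moderated SD of 0.193 per gene.

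The table was fitted in R 4.3.3 with limma 3.58.1, with 1 mean per group over all arrays, 83 residual degrees of freedom and an empirical Bayes prior worth 8.02. Before the data were examined, 24 comparisons were fixed: for each of 5 intervals the change in MCE, the change in RAD and their difference (the interaction), and 9 further comparisons between seed parts, of PE and COT over time and of MCE and RAD at 1 h with dry seed. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison and an absolute log2 difference of at least 1. Tests were two-sided.

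The gene lists were fixed at the same time, 26 lists with 385 entries and 379 genes, of which 345 were measured. Each list was tested with camera in limma with a preset correlation between genes of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, and its members were counted over all genes and adjusted over the list alone. Genes named in the text follow a rule fixed at the same time: in each comparison the 6 called genes with the largest increase and the 6 with the largest decrease whose replicates did not overlap (for averages, with the same sign at every stage, and for interactions with no such condition), up to 3 most changed called members of each list in each direction, and 16 genes of germination named in advance. Of these, genes with a known function were preferred in the text, and after the fits without each array were seen, several genes whose calls were lost there were replaced by others that the rule allows.

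The procedure was tested on data simulated from each gene's group means and spread. For testa rupture in RAD, 89% of genes changed by 1.2 and 100% of those changed by 2 were called, with 1 false call. For the interaction at endosperm rupture these were 80%, 100% and 1, and for MCE minus RAD over 11 stages 100%, 100% and 0. Of 200 random lists camera called 1, which does not test lists whose members move together.

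The alternatives were a filter on the 25% of genes whose highest group mean was lowest (15984 genes kept, above a log2 value of 4.04), a repeated quantile normalization, an added shift of each array by its trimmed mean difference to the average array over the genes above the median level (30% trimmed at each end, the added scaling), an intensity trend in the prior, array weights, the replicate number as a block, no fold minimum, only the groups of a comparison in the fit, an estimated correlation for the lists, and fits without the redone arrays, without the arrays with differing labels and without each array in turn. All were fixed in advance. Principal components were taken of centred, unscaled values of all genes. Counts expected for independent calls are the product of both numbers of calls over the number of genes, for the pairs of comparisons within an interval.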

Results

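Gene expression was measured with Affymetrix arrays in seeds of Arabidopsis thaliana, accession Columbia-0, from the dry state to the emergence of the radicle. Seeds were dissected into 4 parts: the endosperm of the micropylar and the chalazal end (MCE), the rest of the endosperm (PE), the radicle with the axis of the embryo (RAD) and the cotyledons (COT). Whole dry seeds were measured beside them. The arrays formed 28 groups of 4, except for PE at 3 h with 3 arrays. MCE and RAD were sampled at 11 stages: 1, 3, 7, 12, 16 and 20 h after sowing, 25 h in seeds without and in seeds with a ruptured testa (the seed coat), 31 h, and 38 h in seeds without and in seeds with a ruptured endosperm. PE was sampled at 3 and 16 h and COT at 3, 16 and 31 h. Each array gave a log2 value per locus, with array medians between 4.67 and 5.22.

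The first principal component of all arrays held 46.8% of the variance, with dry seed at -156.3 ± 0.7 (SD, n = 4). In RAD the mean score was higher at each later stage, from -136.6 ± 7.8 at 1 h to 115.1 ± 1.2 at 38 h with endosperm rupture. In MCE it went from -154.1 ± 2.3 at 1 h to 74.0 ± 1.1 at 31 h and lay at 64.0 ± 3.0 at 38 h with endosperm rupture. The second held 23.0% and parted the compartments: at that last stage MCE lay at -147.3 ± 4.0 and RAD at -4.9 ± 2.7, whereas at 1 h they lay at -19.5 ± 1.3 and 14.0 ± 3.4. The largest distance on it was reached at 31 h, with MCE at -119.7 ± 8.9 and RAD at 60.8 ± 4.5.

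**Figure D1:**
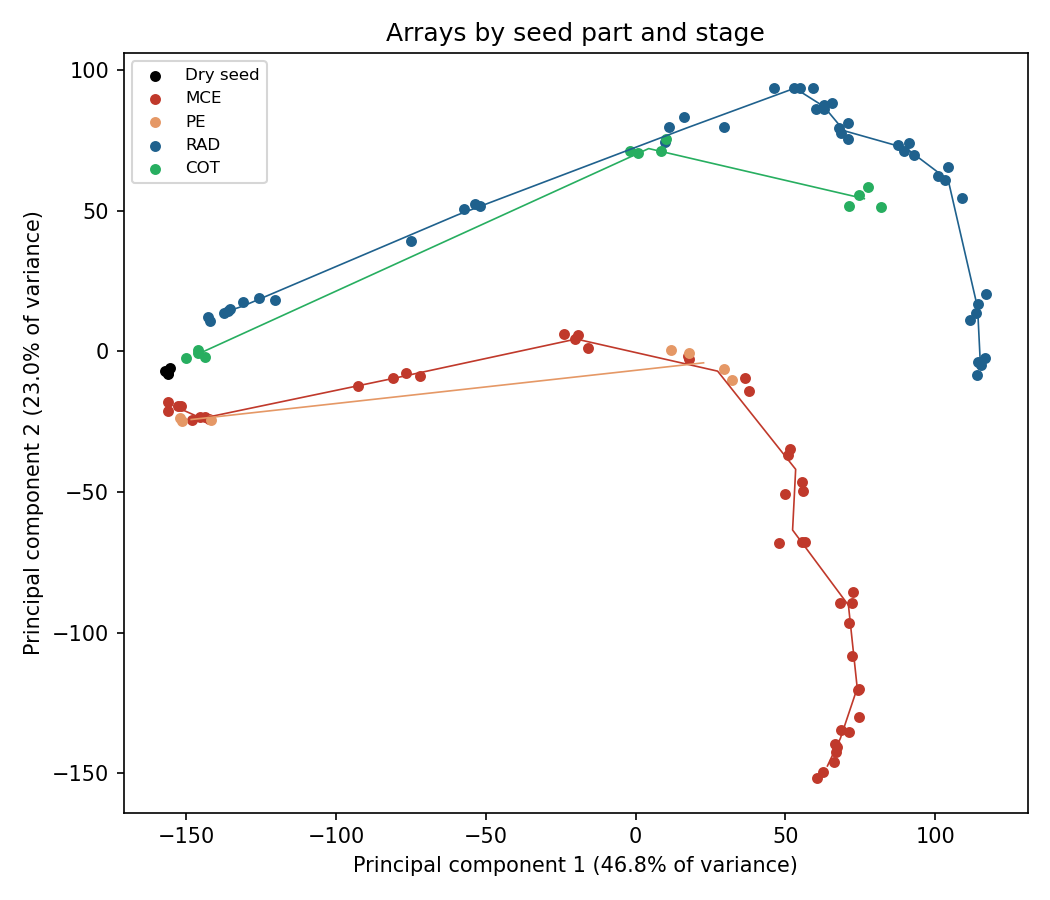
Scores of all arrays on the first (horizontal axis) and second (vertical axis) principal component of the log2 values, with one point per array, coloured by seed part, and lines joining the group means in the order of the stages. Dry seed lies at -156.3 on the first component, and MCE and RAD end at -147.3 and -4.9 on the second.

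A gene is described below as having risen or fallen, or as higher or lower, when its difference passed the thresholds given with the processing. Values in brackets after a gene are log2 differences ± standard error from limma, between group means of 4 arrays each (3 for PE at 3 h), and the loci are given at first mention. For a gene list, the brackets hold the median log2 difference of its measured members and the adjusted p of the set test camera. Where that call was lost with an estimated correlation between genes, the adjusted p with that correlation follows as a second value. Counts of members adjusted over the list alone equalled those over all genes unless given. The standard errors pool a gene's spread over all groups and can understate that of a single group. Near the highest values of the arrays a difference can be understated, and near background it holds no exact size: in 127 of 388 changes of named genes, at least 1 of the groups compared had a mean below 4.04.

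The first interval, from 1 to 12 h, covers the uptake of water and the switch from the transcripts stored in the seed. Among the largest increases in MCE were those of the expansins EXPA1 (AT1G69530, 9.07 ± 0.35), EXPA8 (AT2G40610, 8.51 ± 0.27) and EXPA2 (AT5G05290, 8.17 ± 0.24), which loosen cell walls, of the gibberellin-regulated peptide gene GASA6 (AT1G74670, 8.43 ± 0.40) and of the cysteine proteinase gene CP1 (AT4G36880, 8.69 ± 0.35). At 1 h GASA6 had 4.93 ± 2.21 (SD, n = 4) and EXPA1 3.87 ± 0.96, and the GASA6 difference was 8.03 to 9.53 when 1 array was left out. EXPA2 ended near the highest values of the arrays, so its rise can be understated. Among the largest decreases were HSFA9 (AT5G54070, -7.89 ± 0.16), a heat shock factor of maturing seeds, GolS2 (AT1G56600, -7.08 ± 0.23), a galactinol synthase gene, MIPS2 (AT2G22240, -6.67 ± 0.16), an inositol phosphate synthase gene, and ASN1 (AT3G47340, -6.93 ± 0.17), an asparagine synthetase gene. In all, 5735 genes changed, 3201 upward and 2534 downward, and the adjusted p of each changed gene named for this comparison was 6.28e-10 or less.

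Of the late embryogenesis abundant (LEA) proteins, which protect drying cells, 17 of 19 fell (median -3.16, adjusted p = 4.52e-08 and 0.176), among them EM1 (AT3G51810, -5.74 ± 0.26), ATECP31 (AT3G22500, -5.29 ± 0.26) and EM6 (AT2G40170, -3.87 ± 0.29). Of the seed storage proteins and oleosins, 11 of 15 fell (median -1.64, adjusted p = 0.00155 and 0.455), OLEO3 (AT5G51210, -3.74 ± 0.23) among them, while the cruciferin gene CRA1 (AT5G44120, -0.76 ± 0.28) did not pass. CRA1 lay at 13.83 ± 0.07 (SD, n = 4) at 1 h, near the highest values of the arrays, where a fall can be understated. Small heat shock proteins and HSFA9 fell in 10 of 11 cases (median -4.18, adjusted p = 2.24e-09), among them the chaperone gene HSP101 (AT1G74310, -6.23 ± 0.21). All 16 cytosolic ribosomal protein genes rose (median 2.06, adjusted p = 9.31e-14), with RPL10B (AT1G26910, 3.80 ± 0.16) and RPS6A (AT4G31700, 3.53 ± 0.12) in front. So did 5 of 6 ribosome biogenesis genes (median 1.74, adjusted p = 1.7e-04 and 0.145) such as FIB2 (AT4G25630, 4.29 ± 0.17), and 6 of 14 DNA replication genes (median 0.92, adjusted p = 0.00473 and 0.15) such as PCNA2 (AT2G29570, 3.36 ± 0.19). None of the 9 mitosis genes passed (median -0.17, adjusted p = 0.737).

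Among 22 expansins 9 rose and 1 fell (median 0.25, adjusted p = 4.27e-04). Their median was 0.03 under an added scaling. Among 14 genes of gibberellin signalling and response 8 rose and 2 fell (median 1.20, adjusted p = 0.0152 and 0.176), a call lost with the dim filter (0.0597). In that list the DELLA repressor genes RGA (AT2G01570, 4.74 ± 0.14) and RGL2 (AT3G03450, 3.42 ± 0.14) rose and the receptor genes GID1A (AT3G05120, -1.99 ± 0.14) and GID1C (AT5G27320, -2.10 ± 0.16) fell. Gibberellin synthesis genes moved both ways (median -0.25, mean 0.67, tested as higher, adjusted p = 0.724): the oxidase genes GA20OX3 (AT5G07200, 6.53 ± 0.24) and GA20OX2 (AT5G51810, 5.09 ± 0.32) rose and GA2 (AT1G79460, -1.73 ± 0.16) fell. Of the abscisic acid synthesis genes 4 of 9 fell (median -0.73, adjusted p = 0.0396 and 0.15), led by ABA1 (AT5G67030, -3.84 ± 0.18). The call of the list was lost without replicate 2 of MCE at 12 h (adjusted p = 0.0553), under the added scaling (0.0606) and with array weights (0.0539). The abscisic acid signalling and dormancy list (median -0.21, adjusted p = 0.131) held 4 members that rose and 8 that fell, among them ABI2 (AT5G57050, -4.25 ± 0.17), DOG1 (AT5G45830, -3.18 ± 0.17), a dormancy gene, and ABI5 (AT2G36270, -2.99 ± 0.15). The endo-beta-mannanase gene MAN7 (AT5G66460, 3.99 ± 0.21) rose and MAN1 (AT1G02310, -4.00 ± 0.11) fell (median -0.58, adjusted p = 0.624). Of the genes for storage lipid breakdown and the glyoxylate cycle 5 of 16 rose and 1 fell (median 0.58, adjusted p = 0.00531 and 0.247). Their median was 0.37 under the added scaling.

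The remaining lists did not pass in MCE in this interval. They were abscisic acid catabolism (median -0.47, adjusted p = 0.724), with CYP707A3 (AT5G45340, 2.75 ± 0.38) up and CYP707A2 (AT2G29090, -1.92 ± 0.27) down, gibberellin inactivation (median -0.03, adjusted p = 0.963), xyloglucan endotransglucosylase/hydrolases (median 0.12, adjusted p = 0.529), touch and early wound response (median 0.64, adjusted p = 0.325), jasmonate synthesis and response (median -0.01, mean 0.23, tested as higher, adjusted p = 0.737) and photosynthesis (median -0.24, adjusted p = 0.461). They also included cell death and senescence (median -0.18, adjusted p = 0.724), root meristem and root cap markers (median 0.03, adjusted p = 0.462), root hair genes (median -0.12, adjusted p = 0.566), cotyledon, shoot apex and epidermis markers (median 0.13, adjusted p = 0.363), endosperm markers (median 0.52, adjusted p = 0.285) and seed coat markers (median -0.14, adjusted p = 0.724). Levels of the seed coat markers were low: TT10 (AT5G48100) had 3.12 ± 0.16 (SD, n = 4) in MCE at 12 h.

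In RAD over the same hours, the largest increases included EXPA1 (8.06 ± 0.35), XTH19 (AT4G30290, 7.37 ± 0.46), which remodels xyloglucan, EXPA10 (AT1G26770, 7.35 ± 0.21) and FAD3 (AT2G29980, 7.03 ± 0.32), a fatty acid desaturase gene. The largest decreases were those of GASA2 (AT4G09610, -8.02 ± 0.29), HSFA9 (-7.76 ± 0.16), GolS2 (-7.73 ± 0.23) and MIPS2 (-7.06 ± 0.16). All 19 LEA genes fell (median -4.33, adjusted p = 5.35e-11 and 0.0969). Of the storage protein and oleosin genes 13 of 15 fell (median -2.17, adjusted p = 9.28e-05 and 0.266), CRA1 (-1.45 ± 0.28) among them. DNA replication genes rose in 11 of 14 cases (median 2.64, adjusted p = 7.76e-07), such as PCNA1 (AT1G07370, 3.74 ± 0.18) and MCM2 (AT1G44900, 3.68 ± 0.17). All 16 ribosomal protein genes rose as well (median 1.60, adjusted p = 3.35e-10 and 0.0797). The final enzymes of gibberellin synthesis, encoded by GA3OX1 (AT1G15550, 3.26 ± 0.23) and GA3OX2 (AT1G80340, 5.43 ± 0.18), rose, with 5 of 14 members of that list up (median 0.30, adjusted p = 0.0674). Of the touch and early wound genes 13 of 16 rose (median 2.55, adjusted p = 0.00193 and 0.42), led by XTH22 (AT5G57560, 5.09 ± 0.43) and the calmodulin-like gene CML24 (AT5G37770, 4.28 ± 0.25). Of the root meristem and root cap markers 8 of 17 rose (median 0.89, adjusted p = 0.00837 and 0.0969), among them the auxin carrier gene PIN2 (AT5G57090, 3.54 ± 0.19). Of the abscisic acid signalling genes 3 rose, ABI4 (AT2G40220, 4.51 ± 0.16) the most, and 10 fell (median -1.35, adjusted p = 0.0172 and 0.138), ABI5 (-3.27 ± 0.15), SOM (AT1G03790, -3.13 ± 0.20) and DOG1 (-2.21 ± 0.17) among them. The call of that list was lost with only these groups in the fit (0.0594). The endosperm marker EPR1 (AT2G27380, -1.93 ± 0.18) fell and EXPA2 (0.00 ± 0.24) did not pass in RAD. In total 6163 genes changed, 3578 up and 2585 down (adjusted p of 2.83e-06 or less for each changed gene named).

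The interaction, the change in MCE minus the change in RAD, showed which genes moved differently in the 2 parts. It was largest upward for EXPA2 (8.16 ± 0.34), GASA6 (7.54 ± 0.57), the cytochrome P450 gene CYP71B2 (AT1G13080, 7.50 ± 0.26) and the transporter gene OCT1 (AT1G73220, 6.84 ± 0.30). Among the most negative were those of MYB66 (AT5G14750, -5.10 ± 0.26), a regulator of root epidermis, of GA3OX2 (-5.07 ± 0.26) and of XTH9 (AT4G03210, -4.47 ± 0.54). In the gibberellin synthesis list (median -0.42, adjusted p = 0.0197 and 0.212), GA20OX3 (4.44 ± 0.34) rose more in MCE, whereas GA3OX1 (-3.72 ± 0.33) and GA3OX2 rose more in RAD. The call of that list was lost with the dim filter (0.0656) and with only these groups in the fit (0.0878). DNA replication genes rose more in RAD in 9 of 14 cases (median -1.23, adjusted p = 4.24e-07). So did touch genes in 10 of 16 cases (median -1.74, adjusted p = 6.07e-04 and 0.478, 0 higher and 11 lower adjusted over the list alone), while MAN7 (3.50 ± 0.30) rose more in MCE. Without replicate 2 of MCE at 12 h the touch median was -1.04. LEA genes fell further in RAD in 10 of 19 cases (median 1.16, adjusted p = 9.01e-04 and 0.485, 11 higher and 1 lower adjusted over the list alone), LEA7 (AT1G52690, 3.12 ± 0.42) the most, with EM1 (-2.18 ± 0.36) the other way. Endosperm markers differed as well, with 3 of 4 rising more in MCE (median 1.59, adjusted p = 6.07e-04). Root markers went both ways (median -0.66, adjusted p = 0.00712 and 0.164), with PIN2 (-3.50 ± 0.26) on the RAD side. The interaction passed for 2054 genes (984 more positive in MCE, adjusted p of 7.34e-07 or less for those named). Of the genes called in each part, 2501 rose in both and 2004 fell in both, against 537.4 and 307.3 if the calls were independent.

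After an added scaling of the arrays, the median difference of all genes between 1 and 12 h was -0.285 in MCE and -0.264 in RAD in place of -0.067 and -0.090. The share of changed genes that were higher then moved from 55.8% to 45.3% in MCE and from 58.1% to 49.9% in RAD.

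The second interval, from 12 h to 25 h in seeds whose testa was still closed, covers the run up to testa rupture. In MCE, the gibberellin-regulated gene GASA4 (AT5G15230, 8.85 ± 0.30), the pectin methylesterase gene PMEPCRA (AT1G11580, 7.34 ± 0.39), XTH31 (AT3G44990, 6.97 ± 0.19) and the indole glucosinolate gene CYP79B2 (AT4G39950, 6.61 ± 0.29) rose the most. Genes such as CYP71B14 (AT5G25180, -5.13 ± 0.24), the lactoylglutathione lyase gene GLYI8 (AT2G28420, -5.05 ± 0.27), the amino acid transporter gene UMAMIT22 (AT1G43650, -4.92 ± 0.19) and GA20OX2 (-4.84 ± 0.32) were among those that fell the most. All 15 storage protein and oleosin genes fell (median -2.72, adjusted p = 4.37e-10 and 0.174), among them OLEO4 (AT3G27660, -4.50 ± 0.27), OLEO1 (AT4G25140, -4.12 ± 0.26) and CRA1 (-2.66 ± 0.28). So did 18 of 19 LEA genes (median -2.73, adjusted p = 4.37e-10 and 0.174), among them EM6 (-3.90 ± 0.29), ECP63 (AT2G36640, -3.88 ± 0.35) and M10 (AT2G41280, -3.85 ± 0.27). Ribosome biogenesis turned down in all 6 members (median -2.40, adjusted p = 2.94e-09), FIB2 (-3.08 ± 0.17) and CBF5 (AT3G57150, -2.44 ± 0.15) among them, and 2 of 16 ribosomal protein genes fell (median -0.30, adjusted p = 0.0166 and 0.54). Among the xyloglucan enzymes 11 of 28 rose and 1 fell (median 0.33, adjusted p = 0.00658 and 0.174), with XTH4 (AT2G06850, 3.67 ± 0.27) and XTH18 (AT4G30280, 3.13 ± 0.37) up and XTH25 (AT5G57550, -3.86 ± 0.23) down. Touch genes rose in 9 of 16 cases (median 1.32, adjusted p = 0.01 and 0.54), ERF5 (AT5G47230, 2.82 ± 0.40) and CML38 (AT1G76650, 2.18 ± 0.31) among them. Photosynthesis genes rose in 5 of 17 cases (median 0.48, adjusted p = 0.01 and 0.382), led by PORB (AT4G27440, 3.05 ± 0.31), a chlorophyll synthesis gene. Without replicate 2 of MCE at 12 h, the touch list had a median of 0.85 and an adjusted p of 0.0818. The vacuolar processing enzyme gene delta-VPE (AT3G20210, 4.03 ± 0.19) and the senescence factor gene NAC6 (AT5G39610, 2.55 ± 0.16) rose in a list that did not pass as a whole (median 0.01, adjusted p = 0.0961). MAN7 (1.35 ± 0.21) rose further, and the abscisic acid catabolism genes moved apart, CYP707A1 (AT4G19230, 2.03 ± 0.26) up and CYP707A2 (-2.46 ± 0.27) down. In all 3646 genes changed, 1973 up and 1673 down (adjusted p of 3.45e-08 or less for each changed gene named).

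In RAD, of the storage protein and oleosin genes 14 of 15 fell (median -5.22, adjusted p = 3.82e-28), among them SESA4 (AT4G27170, -6.85 ± 0.43), CRU2 (AT1G03880, -6.06 ± 0.23), OLEO1 (-5.88 ± 0.26) and CRA1 (-5.86 ± 0.28). The LEA list split, with 6 members up and 8 down (median 0.64, mean -0.77, tested as lower, adjusted p = 0.21): LEA7 (4.05 ± 0.30) and AT3G15670 (1.66 ± 0.34) rose, and M17 (AT2G41260, -7.34 ± 0.27), M10 (-6.43 ± 0.27) and RAB18 (AT5G66400, -4.29 ± 0.34) fell. The steepest increases included those of the lectin gene JAL34 (AT3G16460, 5.90 ± 0.23), the beta-glucosidase gene PYK10 (AT3G09260, 5.26 ± 0.29) and NAI2 (AT3G15950, 4.95 ± 0.19), which belong to endoplasmic reticulum bodies, and the histone genes HTA11 (AT3G54560, 4.86 ± 0.19) and AT1G09200 (5.09 ± 0.19). DNA replication genes rose again, 12 of 14 (median 1.44, adjusted p = 5.17e-13), led by TSO2 (AT3G27060, 2.61 ± 0.15), MCM7 (AT4G02060, 2.47 ± 0.22) and PCNA1 (2.41 ± 0.18), but none of the 9 mitosis genes passed (median 0.00, mean -0.06, tested as lower, adjusted p = 0.967). Root meristem and root cap markers rose in 6 of 17 cases (median 0.76, adjusted p = 1.08e-05), PIN4 (AT2G01420, 2.77 ± 0.18), TMO7 (AT1G74500, 2.57 ± 0.18) and TMO5 (AT3G25710, 2.19 ± 0.18) among them. Small heat shock genes fell in 6 of 11 cases (median -1.02, adjusted p = 1.39e-06), led by HSP17.4 (AT3G46230, -5.13 ± 0.28). The expansins EXPA10 (-1.94 ± 0.21), EXPA8 (-1.61 ± 0.27) and EXPA1 (-1.36 ± 0.35) fell, GASA4 (3.21 ± 0.30) rose, and the dormancy gene DOG1 (-1.16 ± 0.17) and MFT (AT1G18100, -3.52 ± 0.26) fell. The number of changed genes was 2066, 1256 up and 810 down (adjusted p of 7.88e-04 or less for each changed gene named). Without the fold minimum 3871 were up and 4063 down.

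The parts moved apart more than in the first interval, with 3050 genes passing the interaction (adjusted p of 8.73e-06 or less for those named). Among the most positive, toward MCE, were the chalcone synthase gene TT4 (AT5G13930, 6.64 ± 0.40), XTH31 (6.55 ± 0.27), the oxygenase gene DMR6 (AT5G24530, 6.47 ± 0.22) and the carboxypeptidase-like gene SCPL51 (AT2G27920, 6.27 ± 0.25). Among the most negative were UMAMIT22 (-5.09 ± 0.27), ECP63 (-4.95 ± 0.49), JAL34 (-4.70 ± 0.32) and LEA7 (-4.69 ± 0.42). LEA genes went lower in MCE relative to RAD in 13 of 19 cases and higher in 2 (median -3.02, adjusted p = 1.63e-05 and 0.282), and storage genes fell further in RAD in 10 of 15 (median 2.47, adjusted p = 4.54e-06 and 0.282). Ribosome biogenesis moved toward RAD in 5 of 6 members (median -2.05, adjusted p = 2.01e-09) and DNA replication in 9 of 14 (median -1.37, adjusted p = 1.03e-06), with FIB2 (-2.80 ± 0.24) and TSO2 (-2.36 ± 0.22) as examples. Xyloglucan enzymes (median 0.36, adjusted p = 7.21e-04 and 0.0992), photosynthesis (median 0.74, adjusted p = 0.00193 and 0.282), touch genes (median 1.39, adjusted p = 0.0065 and 0.529, 11 higher and 0 lower adjusted over the list alone) and cell death and senescence genes (median 0.09, adjusted p = 0.00198) moved toward MCE, with XTH18 (2.92 ± 0.52), PORB (3.29 ± 0.44), ERF5 (2.98 ± 0.57) and delta-VPE (3.94 ± 0.27). Without replicate 2 of MCE at 12 h, the touch genes had a median of 0.82 and an adjusted p of 0.0623. Without replicate 1 of MCE at 25 h the median was 2.11. In both parts 627 genes rose and 414 fell, against 116.3 and 63.6 if the calls were independent.

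**Figure D2:**
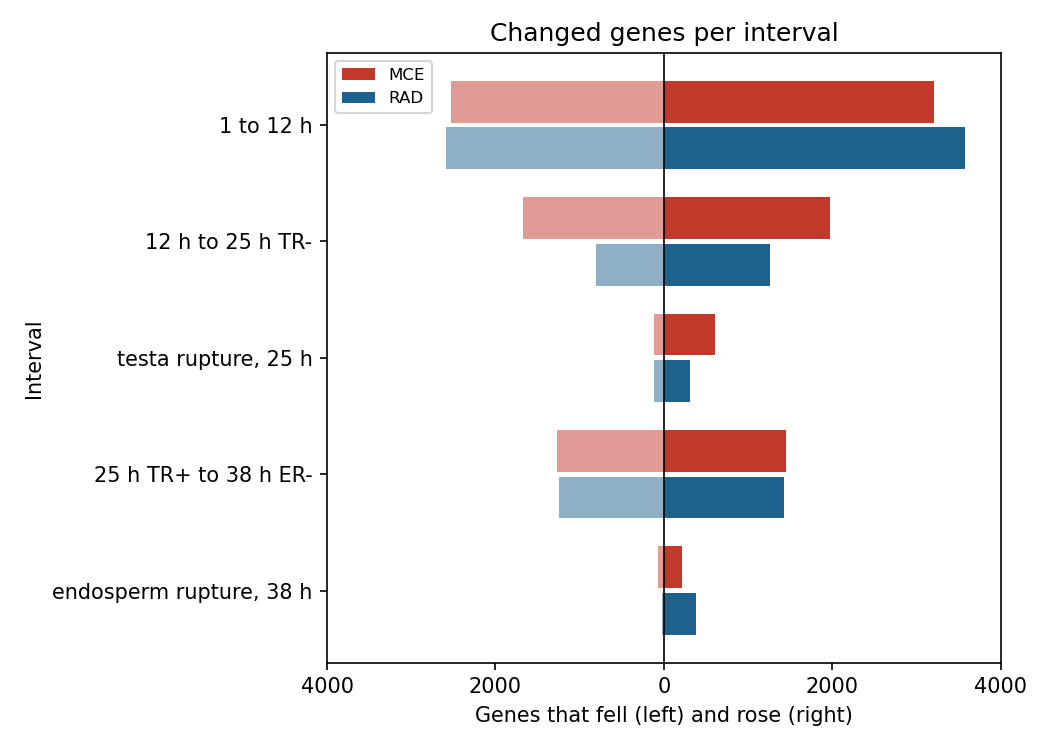
Number of genes that rose (bars to the right) and fell (bars to the left) in each interval in MCE and in RAD, by the thresholds of an adjusted p under 0.05 and a log2 difference of at least 1. The numbers are largest between 1 and 12 h, with 5735 in MCE and 6163 in RAD, and smallest at endosperm rupture, with 281 and 408.

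At 25 h, seeds with a ruptured testa were set against seeds of the same age with a closed testa. In MCE, the largest increases after rupture included those of sks9 (AT4G38420, 5.54 ± 0.23), a multicopper oxidase family member, the arabinogalactan protein genes AGP2 (AT2G22470, 5.50 ± 0.26) and AGP21 (AT1G55330, 4.99 ± 0.27), XTH24 (AT4G30270, 5.19 ± 0.22) and XTH17 (AT1G65310, 4.66 ± 0.20). The decreases were largest for SESA5 (AT5G54740, -3.21 ± 0.42), the seed aquaporin gene TIP3;1 (AT1G73190, -2.97 ± 0.36), CRU3 (AT4G28520, -2.65 ± 0.29) and OLEO2 (AT5G40420, -2.42 ± 0.30). Of the xyloglucan enzymes 12 of 28 were higher (median 0.68, adjusted p = 8.64e-20), XTH23 (AT4G25810, 4.51 ± 0.30) among them. The expansin list did not pass as a whole (median -0.11, mean 0.23, tested as higher, adjusted p = 0.417), but its 3 higher members were the expansin-like genes EXLA1 (AT3G45970, 3.70 ± 0.38), EXLA2 (AT4G38400, 3.90 ± 0.21) and EXLA3 (AT3G45960, 2.32 ± 0.17). Touch and early wound genes were higher in 7 of 16 cases (median 0.91, adjusted p = 1.02e-06 and 0.251), among them CML12 (AT2G41100, 3.30 ± 0.37) and XTH22 (3.03 ± 0.43). Their median was 0.25 without replicate 1 of the seeds with a closed testa. Of the abscisic acid catabolism genes 2 of 4 were higher (median 1.35, adjusted p = 4.93e-04), namely CYP707A1 (2.49 ± 0.26) and CYP707A3 (1.79 ± 0.38). The CYP707A3 difference was 1.15 without that replicate. Storage protein and oleosin genes were lower in 13 of 15 cases (median -1.96, adjusted p = 1.93e-18) and LEA genes in 8 of 19 (median -0.96, adjusted p = 2.75e-07 and 0.251), RAB18 (-1.81 ± 0.34) among them. GASA1 (AT1G75750, 4.56 ± 0.21) and the NAC factor gene ANAC087 (AT5G18270, 2.74 ± 0.15) were higher, and MAN7 (-0.75 ± 0.21) and EXPA2 (-0.22 ± 0.24) did not pass. EXPA2 lay near the highest values of the arrays in both groups (lower mean 14.14), where a difference can be understated. In all 718 genes differed, 603 higher and 115 lower (adjusted p of 1.43e-04 or less for each changed gene named). Without the fold minimum 1660 were higher and 2152 lower.

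In RAD, the genes with the largest increases in seeds with a ruptured testa included the fasciclin-like gene FLA9 (AT1G03870, 3.21 ± 0.19), AGP21 (2.95 ± 0.27), the nitrate reductase gene NIA2 (AT1G37130, 2.85 ± 0.25), the organ size gene ORS1 (AT2G41230, 2.84 ± 0.35) and the invertase gene ATBFRUCT1 (AT3G13790, 2.75 ± 0.22). The largest decreases included SOM (-2.30 ± 0.20), a repressor of light-dependent germination, GA20OX1 (AT4G25420, -2.27 ± 0.21) and the LEA gene AT3G17520 (-2.21 ± 0.36). LEA genes were lower in 14 of 19 cases (median -1.46, adjusted p = 1.44e-18), EM1 (-2.02 ± 0.26) and EM6 (-1.86 ± 0.29) among them. Storage genes were lower in 10 of 15 (median -1.36, adjusted p = 2e-14). Abscisic acid signalling and dormancy genes were lower in 4 of 19 cases (median -0.44, adjusted p = 1.44e-07), AHG1 (AT5G51760, -1.60 ± 0.26) among them, and 2 of 4 catabolism genes were higher (median 0.97, adjusted p = 2.12e-04), CYP707A2 (2.21 ± 0.27) and CYP707A1 (1.16 ± 0.26). The latter was at 0.99 without replicate 2 of the seeds with a closed testa. Xyloglucan enzymes were higher in 11 of 28 cases (median 0.35, adjusted p = 6.98e-12), XTH24 (2.52 ± 0.22), XTH16 (AT3G23730, 2.28 ± 0.28) among them. Touch genes were higher in 3 of 16 (median 0.57, adjusted p = 2.74e-05 and 0.461, 4 higher and 0 lower adjusted over the list alone). The gibberellin synthesis list did not pass (median -0.15, adjusted p = 0.0693): GA3OX1 (1.97 ± 0.23) was higher, and GA20OX1, GA20OX2 (-1.92 ± 0.32) and GA20OX3 (-1.34 ± 0.24) were lower. That list passed without replicate 2 of the seeds with rupture (median -0.20) or replicate 4 of those without (median -0.18). The expansin list split evenly (median -0.02, mean 0.03, tested as higher, adjusted p = 0.807), with EXLA1 (2.16 ± 0.38), EXLA2 (2.01 ± 0.21) and EXPA6 (AT2G28950, 1.37 ± 0.17) higher and EXPA10 (-1.55 ± 0.21), EXPA1 (-1.34 ± 0.35) and EXPA15 (AT2G03090, -1.23 ± 0.21) lower. The number of genes that differed was 430, 307 higher and 123 lower (adjusted p of 0.00428 or less for each changed gene named). Without the fold minimum 1037 were higher and 1017 lower.

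The difference between seeds with and without testa rupture was larger in MCE for 9 of 28 xyloglucan enzymes (median 0.27, adjusted p = 2.16e-07, 10 higher and 0 lower adjusted over the list alone), such as XTH23 (3.22 ± 0.42), XTH17 (3.21 ± 0.28) and XTH24 (2.66 ± 0.31). The same held for GASA1 (4.09 ± 0.30), the sulfotransferase gene SOT12 (AT2G03760, 4.47 ± 0.26) and EXLA3 (1.88 ± 0.25). It was larger in RAD for ORS1 (-2.31 ± 0.50), ATBFRUCT1 (-2.23 ± 0.31) and GA3OX1 (-1.28 ± 0.33). The cell death and senescence list differed in 1 gene (median 0.15, adjusted p = 0.00257 and 0.055), ANAC087 (2.91 ± 0.21), and ribosome biogenesis differed as a list with no member passing (median -0.65, adjusted p = 3.77e-06 and 0.055). The interaction passed for 461 genes (adjusted p of 0.00605 or less for those named). Of the genes called in each part, 177 were higher in both and 39 lower in both, against 8.7 and 0.7 if the calls were independent.

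From 25 h with testa rupture to 38 h in seeds whose endosperm was still closed, the increases in MCE were largest for the cutinase gene CDEF1 (AT4G30140, 6.58 ± 0.16), the phosphoribulokinase gene PRK (AT1G32060, 6.14 ± 0.24), the photosystem I genes PSAG (AT1G55670, 6.10 ± 0.19) and PSAK (AT1G30380, 6.07 ± 0.25), the xylosidase gene BXL1 (AT5G49360, 5.96 ± 0.18) and LHCB3 (AT5G54270, 5.85 ± 0.21), which encodes a light-harvesting protein. Of the photosynthesis genes 14 of 17 rose and 1 fell (median 3.71, adjusted p = 1.15e-20), with LHCA3 (AT1G61520, 5.67 ± 0.22) and PSAF (AT1G31330, 4.73 ± 0.19) up and the regulator gene GLK2 (AT5G44190, -1.32 ± 0.14) down. The cell death and senescence list rose in 5 of 15 members and fell in 1 (median 0.50, adjusted p = 6.14e-04), with the protease genes AT4G04460 (3.72 ± 0.17) and CEP3 (AT3G48350, 2.86 ± 0.16) and the factor gene NAC046 (AT3G04060, 3.33 ± 0.18) up. The sulfate assimilation gene APR1 (AT4G04610, -5.38 ± 0.23), the cytochrome b5 gene CB5-C (AT2G46650, -4.85 ± 0.27) and the sulfotransferase gene SOT17 (AT1G18590, -4.32 ± 0.25) were among those that fell the most. Expansins fell in 11 of 22 cases (median -0.78, adjusted p = 0.00168 and 0.0908), LEA genes in 11 of 19 (median -1.01, adjusted p = 9.61e-04 and 0.541) and ribosomal protein genes in 4 of 16 (median -0.91, adjusted p = 4.56e-09 and 0.118), with EXLA3 (-2.30 ± 0.17), LEA7 (-3.26 ± 0.30) and RPL5B (AT5G39740, -1.39 ± 0.15) as examples. MAN7 (-4.03 ± 0.21), XTH15 (AT4G14130, -3.71 ± 0.39), GA20OX3 (-3.33 ± 0.24), ABI5 (-1.92 ± 0.15), ABI3 (AT3G24650, -1.56 ± 0.15) and the jasmonate synthesis gene AOC4 (AT1G13280, -3.84 ± 0.23) fell. In turn XTH24 (2.41 ± 0.22) and GASA1 (3.55 ± 0.21) rose further. The cotyledon markers did not pass as a list (median 0.23, adjusted p = 0.601): 2 members rose, PHB (AT2G34710, 1.43 ± 0.15) the most, and AIL6 (AT5G10510, -2.75 ± 0.11) and REV (AT5G60690, -1.44 ± 0.10) fell. In all 2709 genes changed, 1443 up and 1266 down (3831 and 5023 without the fold minimum). The adjusted p of each changed gene named was 1.23e-13 or less.

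In RAD over the same interval, all 9 mitosis genes rose (median 2.89, adjusted p = 2.64e-18), among them the cytokinesis gene KNOLLE (AT1G08560, 4.86 ± 0.14), the kinase gene AUR1 (AT4G32830, 3.91 ± 0.16) and CDKB2;1 (AT1G76540, 3.77 ± 0.17). Other large increases were those of the glutamate decarboxylase gene GAD (AT5G17330, 6.42 ± 0.24), the aquaporin gene TIP2 (AT3G26520, 6.29 ± 0.21) and the annexin gene ANNAT1 (AT1G35720, 5.65 ± 0.17). LEA genes fell in 15 of 19 cases (median -2.59, adjusted p = 4.2e-09 and 0.227), AT3G15670 (-4.96 ± 0.34) and LEA4-1 (AT1G32560, -4.48 ± 0.40) the most. Storage genes fell in 9 of 15 cases (median -1.23, adjusted p = 6.24e-04 and 0.461). Ribosome biogenesis genes fell in 5 of 6 cases (median -1.13, adjusted p = 3.66e-05 and 0.164), PUM23 (AT1G72320, -1.55 ± 0.14) among them. In addition 3 of 14 DNA replication genes fell (median -0.66, adjusted p = 0.0733), a list that passed without replicate 4 of the later group (median -0.67). Photosynthesis genes rose in 8 of 17 cases (median 0.84, adjusted p = 5.45e-05 and 0.227), PORB (3.70 ± 0.31) and RCA (AT2G39730, 3.64 ± 0.21) among them. Gibberellin signalling and response fell in 6 of 14 members and rose in 1 (median -0.78, adjusted p = 0.0191 and 0.227), with GASA6 (-2.12 ± 0.40) and RGL3 (AT5G17490, -2.07 ± 0.14) down and GASA4 (3.15 ± 0.30) up. Abscisic acid signalling genes fell in 7 cases and rose in 1 (median -0.46, adjusted p = 0.0236 and 0.227), HAI3 (AT2G29380, -2.45 ± 0.19) and ABI3 (-1.64 ± 0.15) among those that fell. The calls of these 2 lists were lost with the dim filter (0.0504 and 0.0571). XTH31 (3.76 ± 0.19) rose and XTH24 (-3.28 ± 0.22) and EXLA1 (-2.46 ± 0.38) fell. The number of changed genes was 2679, 1431 up and 1248 down (adjusted p of 4.23e-06 or less for each changed gene named).

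The interaction passed for 4017 genes in this interval (adjusted p of 0.00592 or less for those named). Photosynthesis rose more in MCE in 12 of 17 genes and less in 2 (median 2.24, adjusted p = 6.17e-09 and 0.0503), with LHCB3 (5.55 ± 0.29) and PORB (-1.41 ± 0.44) at the ends. All 9 mitosis genes rose more in RAD (median -2.70, adjusted p = 9.1e-13), KNOLLE (-4.43 ± 0.20) the most. CDEF1 (6.60 ± 0.23), XTH24 (5.69 ± 0.31) and UMAMIT17 (AT4G08300, 5.72 ± 0.25) were among those farthest toward MCE and the glucosinolate genes CYP79B2 (-6.97 ± 0.41) and CYP79B3 (AT2G22330, -6.72 ± 0.40) and the jasmonate gene AOC4 (-5.91 ± 0.33) among those farthest toward RAD. MAN7 (-3.91 ± 0.30) and EXPA9 (AT5G02260, -2.95 ± 0.28) moved down in MCE relative to RAD and LEA4-5 (AT5G06760, 3.22 ± 0.51) moved down in RAD relative to MCE. In both parts 386 genes rose and 215 fell, against 96.9 and 74.1 if the calls were independent. A further 136 went opposite ways. Under the added scaling, the median difference of all genes was 0.144 in MCE and 0.101 in RAD, and the share of changed genes that were higher rose from 53.3% to 66.0% and from 53.4% to 65.9%.

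**Figure D3:**
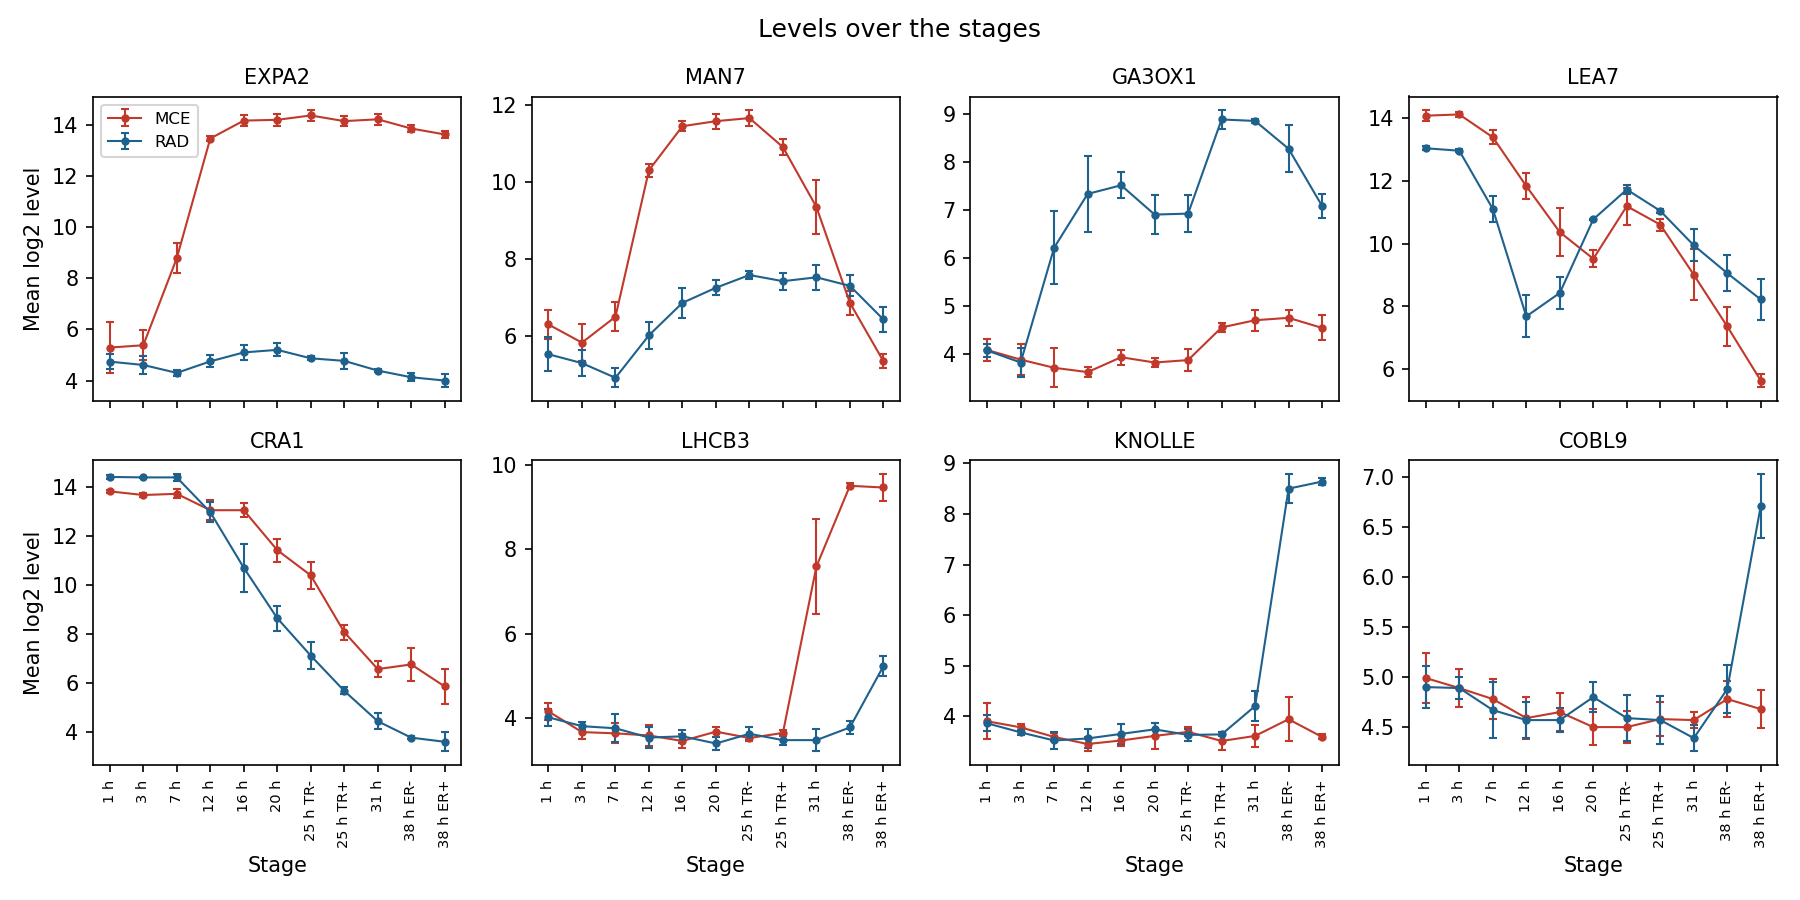
Mean log2 level (vertical axis) of 8 genes over the 11 stages (horizontal axis) in MCE and RAD, with bars of 1 SD over 4 arrays. LHCB3 rises in MCE and KNOLLE in RAD after testa rupture, while EXPA2 stays low in RAD throughout.

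At 38 h, seeds with a ruptured endosperm (radicle emerged) were set against those without. In MCE the largest increases included IGMT2 (AT1G21120, 3.16 ± 0.21), which acts on indole glucosinolates. Others were the trypsin inhibitor gene KTI1 (AT1G73260, 2.74 ± 0.20) and the fatty acid dioxygenase gene DOX1 (AT3G01420, 2.43 ± 0.16). The largest decreases included those of TMO7 (-2.36 ± 0.18), the auxin conjugation genes GH3.1 (AT2G14960, -2.20 ± 0.18) and WES1 (AT4G27260, -1.72 ± 0.17), and LEA7 (-1.73 ± 0.30). Storage genes were lower in 6 of 15 cases (median -0.90, adjusted p = 3.4e-07 and 0.271, 0 higher and 7 lower adjusted over the list alone) and LEA genes in 5 of 19 (median -0.60, adjusted p = 3.27e-05 and 0.41), with SESA3 (AT4G27160, -1.27 ± 0.27) and LEA4-1 (-1.85 ± 0.40) as examples. The cell death and senescence list was higher (median 0.22, adjusted p = 0.018 and 0.162), with 1 member, alpha-VPE (AT2G25940, 1.15 ± 0.15), passing. Its adjusted p was 0.0673 without replicate 1 of the seeds with rupture and 0.064 without replicate 3 of those without. It was 0.126 with the dim filter (median 0.36) and 0.0658 with only these groups in the fit. The ribosomal protein list was lower with no member passing (median -0.36, adjusted p = 2.91e-10 and 0.141). MAN7 (-1.51 ± 0.21) and ABI3 (-1.13 ± 0.15) were lower too. In all 281 genes differed, 211 higher and 70 lower (adjusted p of 5.2e-04 or less for each changed gene named). Without the fold minimum 812 were higher and 842 lower.

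In RAD, root hair genes were higher with endosperm rupture in 4 of 14 cases (median 0.59, adjusted p = 3.7e-13). They included COBL9 (AT5G49270, 1.83 ± 0.15), RHD2 (AT5G51060, 1.66 ± 0.13) and the regulator gene RSL4 (AT1G27740, 1.24 ± 0.14). Jasmonate genes were higher in 5 of 15 cases (median 0.79, adjusted p = 1.51e-07), among them JAZ10 (AT5G13220, 1.70 ± 0.24) and JAZ2 (AT1G74950, 1.40 ± 0.16). Photosynthesis genes were higher in 5 of 17 cases (median 0.66, adjusted p = 1.03e-07), LHCB3 (1.45 ± 0.21) among them. Gibberellin synthesis was lower, with 2 of 14 members passing (median -0.26, adjusted p = 8.38e-04), GA20OX2 (-1.77 ± 0.32) and GA3OX1 (-1.19 ± 0.23). Gibberellin inactivation was higher, with 2 of 7 (median 0.10, adjusted p = 8.38e-04), GA2OX6 (AT1G02400, 1.78 ± 0.27) and GA2OX2 (AT1G30040, 1.34 ± 0.18). Among the largest increases were those of the peroxidase genes AT5G64100 (4.20 ± 0.21) and AT5G17820 (3.53 ± 0.19), and of GSTU12 (AT1G69920, 3.25 ± 0.30), a glutathione transferase gene. Xyloglucan enzymes were higher in 3 of 28 cases (median 0.17, adjusted p = 6.45e-04 and 0.059), XTH7 (AT4G37800, 1.59 ± 0.12) among them. DNA replication was lower as a list with no member passing (median -0.44, adjusted p = 8.19e-05). ABI3 (-1.31 ± 0.15), LEA4-1 (-1.21 ± 0.40) and the cellulase gene CEL5 (AT1G22880, -1.36 ± 0.19) were lower. The LEA4-1 difference did not pass without RAD replicate 1, 2 or 4 of the seeds with rupture (-1.18, -0.93 and -0.91), without replicate 1 or 3 of those without (-0.72 and -0.80), with array weights (-0.94) or with only these groups in the fit (-1.21, adjusted p = 0.391). It was -1.83 without replicate 3 of the seeds with rupture. Of 408 genes that differed, 379 were higher and 29 lower (adjusted p of 0.0354 or less for each changed gene named). Without the fold minimum 1277 were higher and 797 lower.

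Of 422 genes that passed the interaction, 304 were more positive in RAD and 118 in MCE (adjusted p of 1.73e-05 or less for those named). Toward RAD lay AT5G64100 (-4.09 ± 0.30), the phenylpropanoid gene PAL1 (AT2G37040, -3.75 ± 0.30), the actin regulator gene ADF11 (AT1G01750, -3.24 ± 0.15), COBL9 (-1.93 ± 0.21), RHD2 (-1.51 ± 0.19) and JAZ2 (-1.48 ± 0.23), with root hair genes (median -0.43, adjusted p = 3.44e-08) and jasmonate genes (median -0.64, adjusted p = 4.56e-05 and 0.232) as lists. The jasmonate median was between -0.41 and -0.40 without replicate 2 of MCE without rupture, replicate 2 of RAD with rupture or replicate 4 of RAD without. Toward MCE lay KTI1 (2.61 ± 0.29), DOX1 (2.56 ± 0.23), LAC7 (AT3G09220, 2.11 ± 0.17), a laccase gene, and alpha-VPE (1.18 ± 0.21). In both parts 65 genes were higher and 5 lower, against 3.8 and 0.1 if the calls were independent.

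Averaged over the 11 stages, MCE and RAD differed strongly in the endosperm marker EPR1 (8.05 ± 0.05), GASA6 (7.44 ± 0.12), EXPA2 (7.33 ± 0.07) and the oxidase gene SRG1 (AT1G17020, 6.82 ± 0.05), all higher in MCE. It was the reverse for ASL5 (AT2G30130, -5.09 ± 0.05), the growth regulator gene AN3 (AT5G28640, -4.21 ± 0.05) and PIN2 (-4.02 ± 0.06). In all 3426 genes differed, 1667 higher and 1759 lower in MCE (adjusted p of 7.42e-38 or less for those named). Higher in MCE were 12 of 17 photosynthesis genes (median 1.35, adjusted p = 4.5e-06 and 0.0583), 8 of 15 cell death and senescence genes (median 1.03, adjusted p = 8.4e-05) such as delta-VPE (3.82 ± 0.06), 6 of 16 lipid breakdown genes (median 0.80, adjusted p = 4.5e-08) such as PCK1 (AT4G37870, 1.20 ± 0.03). So were 10 of 15 storage genes, with 1 lower (median 1.04, adjusted p = 0.013 and 0.647). Higher in RAD were 10 of 14 DNA replication genes (median -1.74, adjusted p = 2.49e-06) such as PCNA1 (-2.83 ± 0.05), 7 of 16 ribosomal protein genes (median -0.99, adjusted p = 1.19e-08 and 0.0583), 9 of 17 root markers (median -1.17, adjusted p = 1.51e-04) such as PLT2 (AT1G51190, -2.47 ± 0.05). The same held for 8 of 14 gibberellin synthesis genes with 1 higher in MCE (median -1.10, adjusted p = 0.00368 and 0.0583). GA3OX2 (-3.44 ± 0.06) and GA3OX1 (-2.76 ± 0.07) were higher in RAD and GA20OX3 (1.62 ± 0.07) in MCE. The genes MAN7 (2.17 ± 0.06), XTH31 (5.49 ± 0.06) and NCED9 (AT1G78390, 1.50 ± 0.06) were higher in MCE and ABI4 (-3.39 ± 0.05) in RAD. The endosperm list was higher in MCE (median 4.13, adjusted p = 0.013).

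At 1 h, 1167 genes already differed, 616 higher and 551 lower in MCE. Higher in MCE were the latex protein-like gene MLP31 (AT1G70840, 8.63 ± 0.23), CYP714A1 (AT5G24910, 7.06 ± 0.17), EPR1 (6.10 ± 0.18) and, of the abscisic acid synthesis genes, 3 of 9 (median 0.84, adjusted p = 0.00153), among them NCED2 (AT4G18350, 1.37 ± 0.16) and NCED9 (1.14 ± 0.21). Lower were AN3 (-4.30 ± 0.16), the auxin response gene IAA2 (AT3G23030, -3.77 ± 0.19), GA20OX3 (-2.84 ± 0.24) and 4 of 16 ribosomal protein genes (median -0.83, adjusted p = 1.18e-14), RPL10B (-1.46 ± 0.16) among them. DOG1 (1.13 ± 0.17) was higher in MCE. The expansin gene EXPA2 (0.55 ± 0.24) did not pass (adjusted p of 6.13e-06 or less for each gene named as different).

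At 38 h with endosperm rupture, 6745 genes differed, 2998 higher and 3747 lower in MCE (adjusted p of 3.77e-06 or less for each gene named as different). EXPA2 (9.63 ± 0.24), NAC047 (AT3G04070, 9.14 ± 0.18), SRG1 (9.04 ± 0.16), EPR1 (8.88 ± 0.18), GASA6 (8.66 ± 0.40) and XTH24 (8.48 ± 0.22) were higher in MCE. Of the cell death and senescence genes 10 of 15 were higher and 1 lower (median 2.42, adjusted p = 1.79e-06), with delta-VPE (6.82 ± 0.19), NAC046 (5.70 ± 0.18) and NAC6 (3.99 ± 0.16) among them. Of the photosynthesis genes 13 of 17 were higher (median 3.50, adjusted p = 1.33e-08), LHCA1 (AT3G54890, 4.91 ± 0.18) the most. All 16 ribosomal protein genes (median -2.14, adjusted p = 8.55e-12), 8 of 9 mitosis genes (median -2.60, adjusted p = 1.79e-06) and 11 of 14 DNA replication genes (median -2.01, adjusted p = 5.53e-05) were lower in MCE, with KNOLLE (-5.05 ± 0.14) and PCNA1 (-2.77 ± 0.18) as examples. Genes of jasmonate synthesis such as AOC3 (AT3G25780, -4.27 ± 0.25) and OPR3 (AT2G06050, -3.54 ± 0.16) were lower in a list that did not pass (median -0.37, adjusted p = 0.236), and MAN7 (-1.08 ± 0.21) was lower in MCE at this stage, with -0.99 without replicate 1 or replicate 3 of RAD.

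**Figure D4:**
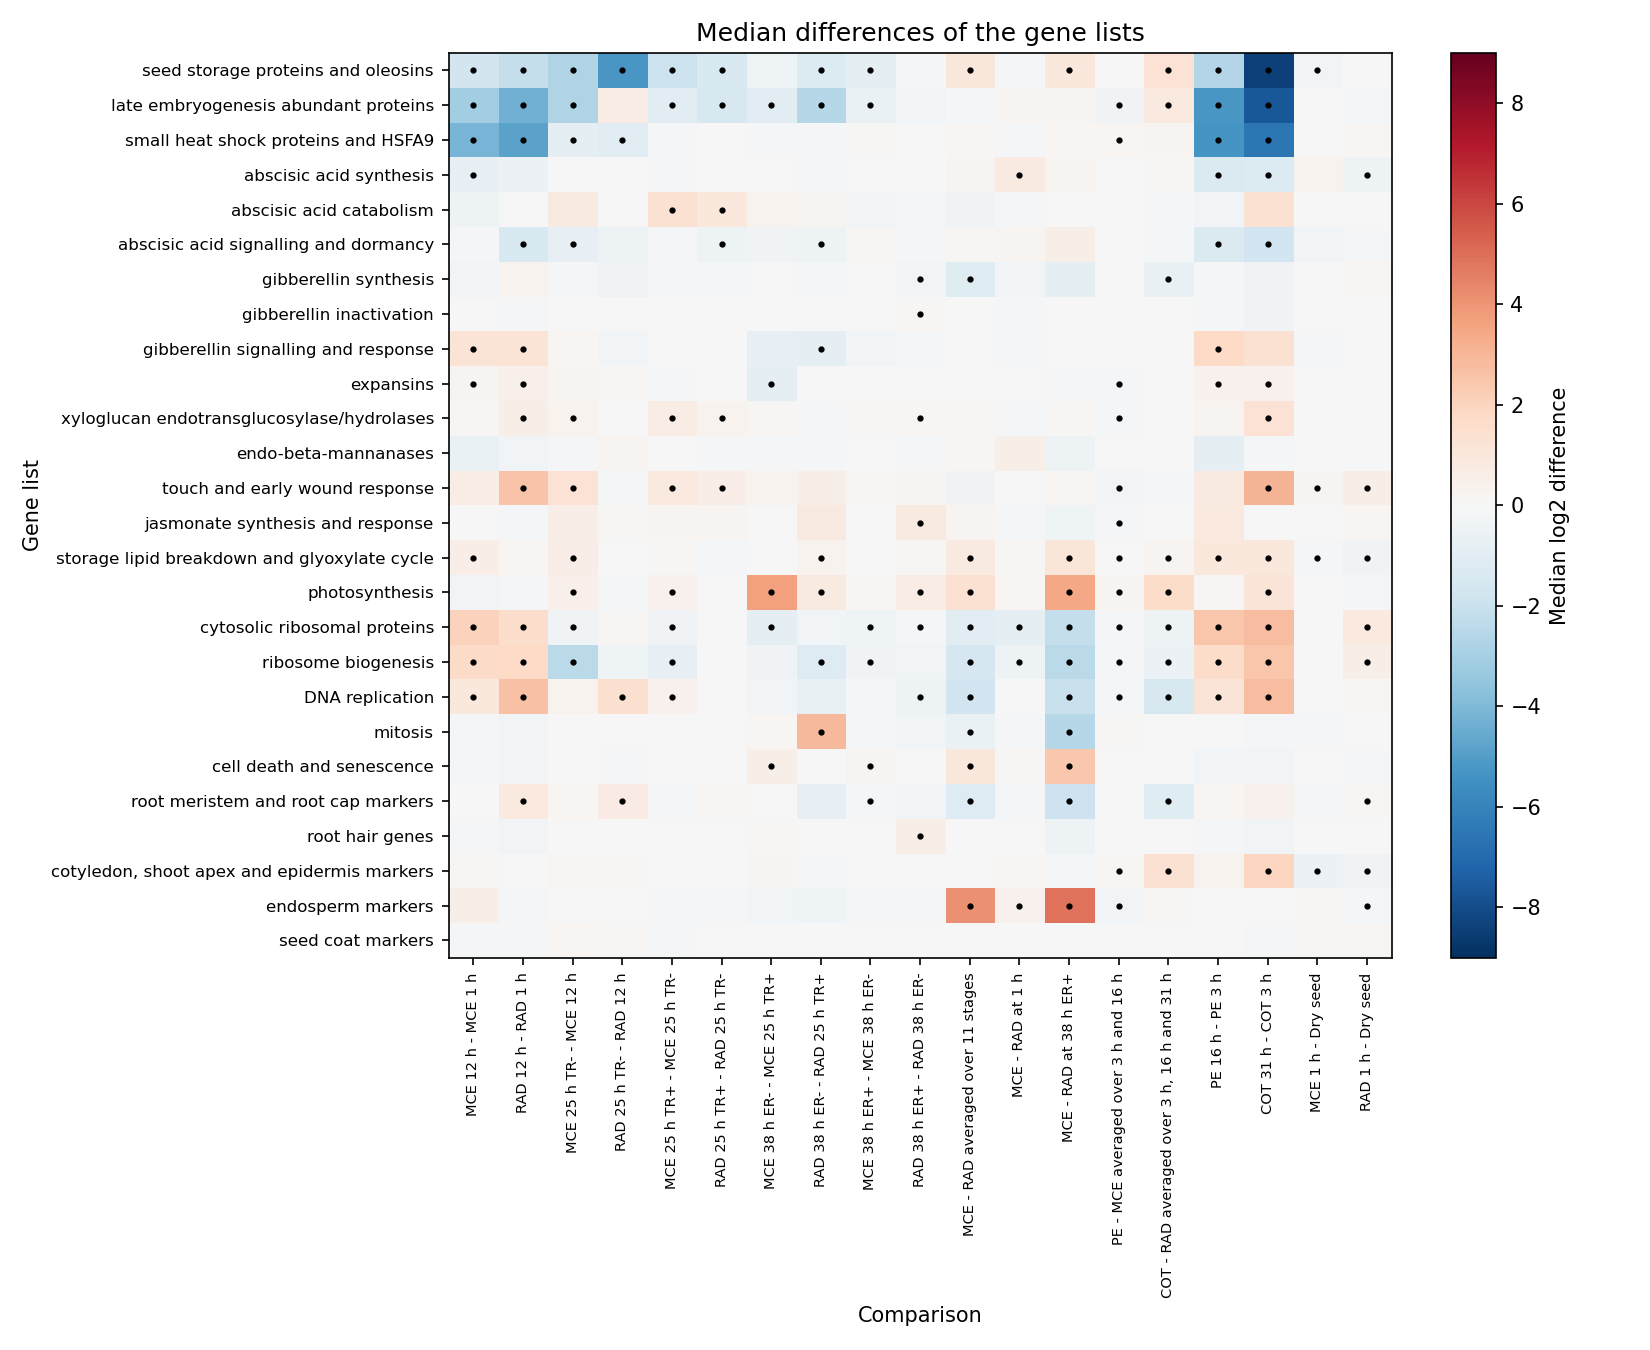
Median log2 difference (colour) of the measured members of each of the 26 gene lists (vertical axis) in 19 comparisons between stages or parts (horizontal axis), with a dot where the set test camera passed an adjusted p of 0.05. The highest median is that of the endosperm markers in MCE against RAD at 38 h with endosperm rupture, at 4.91, and the lowest that of the storage list in COT from 3 to 31 h, at -8.42.

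Averaged over 3 and 16 h, the 2 endosperm samples, PE and MCE, differed in 61 genes, of which 11 were higher and 50 lower in PE (549 and 523 without the fold minimum). Lower in PE were the glucosyltransferase gene UGT71B8 (AT3G21800, -2.48 ± 0.11), the homeobox gene HB-3 (AT2G33880, -2.45 ± 0.11), TMO7 (-2.44 ± 0.13), the defence regulator gene WRKY75 (AT5G13080, -2.44 ± 0.16), XTH24 (-1.18 ± 0.16) and JAZ10 (-1.21 ± 0.18). Higher were CYP71B4 (AT3G26280, 1.26 ± 0.10) and the defensin-like gene LCR69 (AT2G02100, 1.25 ± 0.13) (adjusted p of 3.42e-07 or less for each gene named as different). The endosperm genes EPR1 (0.01 ± 0.13), EXPA2 (-0.44 ± 0.18) and MAN7 (-0.29 ± 0.15) did not pass. At 16 h EXPA2 lay near the highest values of the arrays. The 13 lists that passed had medians between -0.33 and 0.25, the LEA list (median -0.33, adjusted p = 5.81e-04 and 0.307) and photosynthesis (median 0.25, adjusted p = 7.61e-04 and 0.307) at the ends, and none kept its call with an estimated correlation.

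In PE itself, 6316 genes changed from 3 to 16 h, 3522 up and 2794 down. GASA6 (10.63 ± 0.43), EXPA1 (9.44 ± 0.38), EXPA2 (9.10 ± 0.26), the raffinose synthase family gene DIN10 (AT5G20250, 8.85 ± 0.37) and MAN7 (6.38 ± 0.23) rose, EXPA2 again to near the highest values. In contrast GolS2 (-8.05 ± 0.25), XTH25 (-7.78 ± 0.25), MIPS2 (-7.48 ± 0.18), DOG1 (-4.24 ± 0.19), CYP707A2 (-5.80 ± 0.29) and NCED9 (-3.70 ± 0.23) fell (adjusted p of 1.76e-27 or less for each gene named). All 19 LEA genes fell (median -5.26, adjusted p = 1.97e-12 and 0.0697), as did all 15 storage genes (median -2.65, adjusted p = 3.13e-05 and 0.259) and 7 of 9 abscisic acid synthesis genes (median -1.29, adjusted p = 0.00419). All 16 ribosomal protein genes rose (median 2.52, adjusted p = 2.03e-14), and 9 of 22 expansins rose and 1 fell (median 0.36, adjusted p = 4.25e-04). Under the added scaling the expansin median was 0.17, the median of all genes was -0.267 and the higher share moved from 55.8% to 47.7%.

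Averaged over 3, 16 and 31 h, COT and RAD differed in 1668 genes, 931 higher and 737 lower in COT (4837 and 5782 without the fold minimum). Higher in COT were the leaf polarity genes YAB3 (AT4G00180, 5.30 ± 0.11) and FIL (AT2G45190, 5.05 ± 0.10), STOMAGEN (AT4G12970, 5.01 ± 0.10), which promotes stomata, the chloroplast regulator gene CGA1 (AT4G26150, 4.63 ± 0.10) and TCP2 (AT4G18390, 3.77 ± 0.07). Lower were ASL5 (-5.21 ± 0.09), AHL22 (AT2G45430, -4.46 ± 0.09), TMO7 (-4.29 ± 0.10) and PLT2 (-2.73 ± 0.10) (adjusted p of 2.12e-14 or less for each gene named). The cotyledon markers were higher in 11 of 18 cases and lower in 1 (median 1.39, adjusted p = 1.28e-08), photosynthesis genes higher in 10 of 17 (median 1.65, adjusted p = 1.21e-10), PSBP1 (AT1G06680, 2.58 ± 0.10) among them. Root markers were lower in 9 of 17 (median -1.07, adjusted p = 1.54e-09). DNA replication was lower in 9 of 14 members (median -1.46, adjusted p = 3.81e-07), and gibberellin synthesis in 5 of 14 (median -0.69, adjusted p = 2.7e-04), KAO2 (AT2G32440, -2.59 ± 0.07) and GA3OX1 (-1.78 ± 0.13) among them. Storage genes were higher in 10 of 15 cases (median 1.29, adjusted p = 1.39e-05 and 0.335), CRA1 (1.52 ± 0.16) among them.

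COT changed more than any other comparison made: 7948 genes between 3 and 31 h, 4615 up and 3333 down (7036 and 8183 without the fold minimum). All 15 storage genes fell (median -8.42, adjusted p = 9.24e-13), SESA5 (-9.90 ± 0.42), OLEO1 (-9.34 ± 0.26) and CRA1 (-8.42 ± 0.28) among them. So did all 19 LEA genes (median -7.65, adjusted p = 4.98e-13), EM6 (-9.59 ± 0.29) and M17 (-9.31 ± 0.27) among them. XTH9 (8.05 ± 0.38), TUA6 (AT4G14960, 7.87 ± 0.34), a tubulin gene, PDF1 (AT2G42840, 5.90 ± 0.18), FIL (5.05 ± 0.18), PORC (AT1G03630, 5.86 ± 0.17) and RCA (4.16 ± 0.21) rose (adjusted p of 5.44e-34 or less for each gene named). The cotyledon list rose in 14 of 18 cases and fell in 1 (median 1.91, adjusted p = 1.58e-05), DNA replication in 13 of 14 (median 2.77, adjusted p = 2.06e-06), ribosomal protein genes in all 16 (median 2.76, adjusted p = 5.03e-12), and photosynthesis genes in 9 of 17 (median 1.13, adjusted p = 0.00164 and 0.208). Under the added scaling the median of all genes was -0.28.

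The dry seed was measured whole, so the comparisons of MCE and RAD at 1 h with it also hold the difference between a part and the whole seed. In MCE the mitochondrial carrier gene DIC2 (AT4G24570, 3.94 ± 0.34), the calcium and stress genes CML24 (3.49 ± 0.25) and ZAT12 (AT5G59820, 3.38 ± 0.27) and TMO7 (2.95 ± 0.18) were higher than in dry seed, and AN3 (-3.50 ± 0.16) and the leaf gene YAB3 (-3.14 ± 0.18) lower. In all 715 genes differed, 386 higher and 329 lower (adjusted p of 2.43e-17 or less for those named). The cotyledon markers were lower in 4 of 18 cases (median -0.56, adjusted p = 9.85e-06) and touch genes higher in 4 of 16 (median 0.23, adjusted p = 0.0101 and 0.989). In RAD, DIC2 (3.81 ± 0.34), CML24 (2.29 ± 0.25), XTH22 (2.16 ± 0.43) and ZAT12 (1.93 ± 0.27) were higher and MLP31 (-8.00 ± 0.23), CYP714A1 (-5.80 ± 0.17), EPR1 (-5.73 ± 0.18) and YAB3 (-4.17 ± 0.18) lower, with 685 genes in all, 329 higher and 356 lower (adjusted p of 3.61e-05 or less for those named). Ribosomal protein genes were higher in 3 of 16 cases (median 0.85, adjusted p = 5.6e-20). The cotyledon (median -0.30, adjusted p = 7.9e-06) and endosperm markers (median -0.10, adjusted p = 0.00803) were lower as lists. The endosperm markers were not with only these groups in the fit (0.0713). In both parts 51 genes were higher than in dry seed and 71 lower. Another 96 were higher in MCE and lower in RAD and 29 the reverse. Independent calls would give 6 and 5.5 for the genes in both, and simulated unchanged groups gave 0. Both differences share the same dry seed arrays. With the dry seed arrays divided between the 2 comparisons, the numbers higher and lower in both were between 40 and 48 and between 66 and 70.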

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

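The counts for other splits of the arrays, the tests against cotyledon, axis and endosperm levels and the test of the step from 31 to 38 h were chosen only after the results were seen.

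In each of the 5 intervals, the change in MCE differed from the change in RAD by the test of the interaction in limma. The numbers of genes were 2054 from 1 to 12 h, 3050 from 12 to 25 h, 461 at testa rupture, 4017 from 25 to 38 h and 422 at endosperm rupture. As a check against chance, arrays were drawn anew over the 4 groups of each interaction after the additive differences between stages and between compartments were taken off. The real grouping was the 1 of 100 draws with as many genes each time. The highest others, 1269, 1079, 179, 2505 and 86 in that order, can keep part of the real difference. The medians were 0 or 1. This argues against a random division of the arrays, though no share under 1 in 100 could be reached. Seed batches were not given, so they could not be tested.

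The other comparisons were checked the same way. For the changes from 1 to 12 h, the real split of the arrays into groups was the 1 of 35 with as many genes, with 5735 against a highest other of 2402 in MCE and 6163 against 2850 in RAD. The same held for 12 to 25 h (3646 against 1517 in MCE, 2066 against 630 in RAD), testa rupture (718 against 302, 430 against 75), 25 to 38 h (2709 against 898, 2679 against 722) and endosperm rupture (281 against 89, 408 against 154). It also held for MCE against RAD at 1 h (1167 against 361) and at 38 h with endosperm rupture (6745 against 2993), for PE over time (6316 against 4875), COT over time (7948 against 4286), and MCE and RAD at 1 h against dry seed (715 against 151, 685 against 165). With labels drawn within each stage, it was the 1 of 100 for MCE against RAD over all stages (3426 against 332), PE against MCE (61 against 33) and COT against RAD (1668 against 1344). The highest others keep part of the real difference, so are no chance level. Medians of the others were 0 to 25, which argues against a random division in each. No share under 1 in 35 or 1 in 100 could be reached, and the shares were not adjusted. Seed batches cannot be told apart.

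Within groups of 4 arrays, 7 of 77 tests for a value apart from the rest passed Dixon's limit, and chance gives about 1 in 20 groups. On the first component MCE at 31 h replicate 4 scored 72.37, with the others between 74.32 and 74.7. On the second component RAD at 7 h replicate 3 scored 39.1 (others 50.66 to 52.28), MCE at 25 h without testa rupture replicate 1 scored -50.59 (others -67.97 to -67.62) and COT at 16 h replicate 4 scored 75.26 (others 70.61 to 71.17). The first 3 of these arrays were redone per the labels. The level of LHCB3 in COT at 31 h was 4.02 in replicate 1 and 4.78 to 4.92 in the others. In MCE at 1 h GASA6 was at 8.25 in replicate 2 (3.74 to 3.93 in the others) and CRA1 at 13.93 in replicate 4 (13.77 to 13.80).

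The rise of photosynthesis transcripts in MCE between 25 h with testa rupture and 38 h without endosperm rupture was weighed, with 14 of 17 members up. The lower of its medians after quantile normalization or the added scaling was 3.76, beside 3.71, which argues against scaling between arrays as the cause. RNA of cotyledons or axis in the MCE samples was argued against up to 31 h: 13 of the 14 members lay above their RAD level and above the COT level that a share of 5.85% allows, the share set by 20 of 894 genes abundant in COT. LHCB3 had 7.59 ± 1.13 (SD, n = 4) in MCE, 4.65 ± 0.42 in COT and 3.48 ± 0.26 in RAD, and the exception was PORC, with 5.58 ± 0.33 in MCE and 9.72 ± 0.06 in COT. The further median rise of 1.40 from 31 to 38 h cannot be told apart from RNA of cotyledons, because no COT sample was taken at 38 h, and no biological explanation was tested beyond the compartments, so the cause of the rise stays open.

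The rise of 6 of 19 LEA members in RAD from 12 h to 25 h without testa rupture was weighed, with 8 down. The 6 were picked for rising, so 1.62, their lowest median under quantile normalization or the added scaling, cannot test scaling. All 6 lay above their MCE level at 20 h, and 5 at 25 h without testa rupture, which argues against RNA of the endosperm. A first test went toward RNA of cotyledons, since 18 genes high in COT and lower in RAD had a median change of 0.73 (quartiles 0.52 and 0.93, 17 higher), and it was replaced after its result was seen. In the test that replaced it, all 6 members lay above the higher of their COT levels at 16 and 31 h reduced to the share of 29.2% that 20 of 716 genes abundant in COT allow, and the cotyledon gene FIL had 4.20 ± 0.36 in RAD against 10.41 ± 0.16 in COT at 16 h. The earlier test keeps a small share of cotyledon RNA in view and COT was not sampled at 25 h, so a change within the axis is a candidate explanation only as a hypothesis, found and tested on the same data.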

How the results depend on the processing

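All alternatives were planned, and only the tests of calls kept without each array, over all called genes, and of labels swapped within replicate numbers were chosen after results were seen.

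Each of the 24 counts of changed genes stayed within 1.5 times its value under the filter on dim genes (ratios 0.99 to 1.02), repeated quantile normalization (0.98 to 1.09), the added scaling (0.98 to 1.06), the intensity trend (1 to 1.01), array weights (0.89 to 1.1), the fits without the 6 redone arrays (0.83 to 1.06) or the 3 arrays with differing labels (0.97 to 1.15), and the fit of only the groups compared (0.89 to 1.02). With the replicate number as a block, the 24 ratios were 1 to 1.01. The replicate numbers share no stated batch. Residuals correlated by 0.051 on average with the same number and -0.017 with others. Of 30 pairs of groups, PE and MCE at 16 h alone had every pair above 0.1 (0.265 to 0.425, 3 of 4 best with their own number). PE and MCE at 3 h had -0.027 to 0.068. MCE and RAD at 38 h with endosperm rupture and COT and RAD at 16 h had 4 of 4 best. The others had fewer, down to 0 of 4. Labels of PE and MCE were then swapped only within numbers at 16 h and in every split at 3 h. The real ones were the 1 of 560 with as many genes (61 against 51, median 0). Tests between parts were unpaired, and a block for shared numbers changed no named call.

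Without the fold minimum every count rose, because genes with smaller differences then count. In the order MCE, RAD and interaction, the numbers were 12084, 13020 and 5125 from 1 to 12 h, 9569, 7934 and 6985 from 12 to 25 h, 3812, 2054 and 1166 at testa rupture, 8854, 9292 and 8573 from 25 to 38 h, and 1654, 2074 and 913 at endosperm rupture. They were 15341 for MCE against RAD over all stages, 6217 at 1 h and 12680 at 38 h with endosperm rupture, 1072 for PE against MCE, 10619 for COT against RAD, 12184 for PE and 15219 for COT over time, and 4515 and 5283 for MCE and RAD at 1 h against dry seed.

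In 334 counts, each from a comparison fitted leave-one-out over its arrays, no count moved by more than 1.5 times. The widest ranges were 596 (without MCE 25 h without testa rupture replicate 1) to 824 (without replicate 2 of that group) for testa rupture in MCE, beside 718, and 389 to 515 without the same arrays for its interaction, beside 461. Over all called genes, 97.9% of the calls were kept in these fits and 0 were reversed, with the lowest shares at 79.2% for the interaction at testa rupture and 80.6% for testa rupture in MCE, both without MCE 25 h without testa rupture replicate 1, and 82.2% for endosperm rupture in MCE. For the genes named in the text, 5261 of 5269 calls were kept in these fits, a share raised by the replacement of genes whose calls had been lost. Losses are given where the genes are named. Under the other alternatives, LEA4-1 at endosperm rupture in RAD was lost with array weights and with only the groups compared, and the other named calls were kept.

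Of 624 list tests, 205 passed, and 187 to 216 under the other settings, but 72 with an estimated correlation, which allows for members that move together. Of 123 list calls given in the text, 63 were kept with the estimated correlation and 0 were reversed under any alternative. The dim filter ended 5: gibberellin synthesis in the interaction from 1 to 12 h (adjusted p = 0.0656), gibberellin signalling in MCE in that interval (0.0597) and in RAD from 25 to 38 h (0.0504), abscisic acid signalling in RAD from 25 to 38 h (0.0571), and cell death at endosperm rupture in MCE (0.126). With only the groups compared, 4 ended: the first (0.0878) and the last (0.0658) of these, endosperm markers in RAD against dry seed (0.0713) and abscisic acid signalling in RAD from 1 to 12 h (0.0594). Abscisic acid synthesis in MCE from 1 to 12 h ended with array weights (0.0539) and with the added scaling (0.0606). Of the lists that passed, the dim filter moved 15 medians away from 0 by over 1.5 times because dim members left the list, such as 1.43 beside 0.68 for xyloglucan enzymes at testa rupture in MCE. Moves of that size without 1 array are given with the results where the median was at least 0.4 in size. Lists that passed only under an alternative were touch genes in MCE from 1 to 12 h without the 6 redone arrays (0.03), gibberellin synthesis in RAD from 1 to 12 h with array weights (0.0459), the dim filter (0.0498) and without the redone arrays (0.0442), the same list at testa rupture in RAD with quantile normalization (0.0449) and without the redone arrays (0.00915), and DNA replication in RAD from 25 to 38 h with only the groups compared (0.0253) and the added scaling (0.0466).

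The added scaling moved arrays by -0.23 to 0.158 and shifted the balance between higher and lower genes in the intervals named with the results. It set the median of all genes at 0.112 for MCE against RAD at 38 h with endosperm rupture. Array weights lay between 0.265 and 2.71. The first 2 principal components held 46.4% to 47.3% and 23.1% to 23.4% under the alternatives run for them. An alternative with all probe sets of a gene would have repeated the fit, since each locus had 1 probe set, and was not run. Signal near background limits the results: 15984 genes lay above the dim filter at 4.04, and for genes below it a difference cannot be parted from background by these values. Where only some of the groups compared lie below it, the direction can be read and the size of the difference cannot.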

Other observations

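No tests of hypotheses are reported in this part, only values, chosen after the results were seen.

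Stages between those compared showed the order of changes. In MCE the expansin gene EXPA2 had 5.38 ± 0.58 (SD, n = 4) at 3 h, 8.78 ± 0.59 at 7 h and 14.16 ± 0.21 at 16 h, while in RAD it had 5.10 ± 0.29 at 16 h. The mannanase gene MAN7 in MCE had 6.51 ± 0.37 at 7 h, 11.57 ± 0.19 at 20 h and 9.35 ± 0.69 at 31 h. The gibberellin oxidase gene GA3OX1 in RAD had 3.82 ± 0.30 at 3 h and 6.21 ± 0.76 at 7 h, and in MCE 3.71 ± 0.41 at 7 h. The cytokinesis gene KNOLLE in RAD had 4.20 ± 0.29 at 31 h and 8.50 ± 0.29 at 38 h without endosperm rupture.

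Of the 603 genes higher in MCE with testa rupture at 25 h, 299 had a lower mean at 31 h, 40 of them by at least 1 on the log2 scale, 110 had one higher by at least 1, and the median difference was 0.01. Of the 307 such genes in RAD, 147 were lower at 31 h, 21 by at least 1, 47 were higher by at least 1, and the median was 0.06.

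At 16 h the arrays numbered 1 and 2 had first component scores of 37.76 and 36.57 in MCE and 32.04 and 29.35 in PE, while replicate 4 had 17.42 in MCE, with replicate 3 close to it, and replicates 3 and 4 had 17.69 and 11.69 in PE. In RAD at 16 h the scores of replicates 1 to 4 were 52.76, 54.81, 46.05 and 59.07. In 3 arrays, all numbered 2, the title and another label give different hours. The array titled MCE at 16 h scored 36.57 on the first component, against -23.85 to -15.91 in MCE at 12 h. The one titled 20 h scored 55.76, against 50.93 to 55.51 in the other 20 h arrays and 17.42 to 37.76 at 16 h. The one titled 25 h without testa rupture scored -67.62 on the second component, with the others of that title between -67.97 and -50.59 and MCE at 20 h between -49.65 and -34.86, while the first component did not part these 2 groups.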
